A study of Mus musculus with 22 samples.

How the data were processed

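RNA was measured by sequencing in astrocytes of newborn mice that had been isolated on magnetic columns with an antibody against ACSA-2, per the labels. The cells came from cortex at postnatal day 6 or from spinal cord at day 2 or 3, and were lysed directly or after 7 days in medium with 10% serum, 2% B27 and 10 ng/ml EGF and FGF, trypsin and replating. The labels' protocols name a small-sample RNA kit and standard Illumina libraries from total RNA. The aligner, the counting tool, its use of strand, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

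The authors deposited 1 table of normalised counts per gene and library, a signal that is never negative, for 28798 Ensembl mouse genes, of which 28586 could be given a symbol from a reference annotation used only for names. Every value of a library was a whole multiple of 1 step (100% of values within a tolerance of 1e-09), so the deposited values are read counts divided by 1 size factor per library, and dividing by the step gave back whole reads. The recovered factors followed those of DESeq2 with a Pearson r of 0.9999996. Column names were matched to the index sequence in each sample's label. Of 22 labelled libraries 21 were matched, and 1 column matched no label and was not used, so 1 spinal cord culture library was not analysed here and that group holds 5 of its 6 libraries. Recovered depth ran from 150498 to 5777736 reads per library with a median of 1519423, a ratio of 38.4, so genes of low level were measured least precisely in the shallow spinal cord acute libraries. Between libraries of a group, a chi-square test of the reads over genes gave 1.39 to 22.0 per degree of freedom, and no library was a copy of another. The lowest Pearson correlation within a group was 0.769, in spinal cord acute, across genes, which are not independent replicates.

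Genes with a normalised count of at least 5 in at least 5 libraries were kept (14019). Log2(value + 1) was fitted with limma (lmFit, then eBayes with a mean-variance trend) in 1 model with a mean per group, so that the groups share 1 estimate of the spread, and Benjamini-Hochberg adjusted p-values under 0.05 over all kept genes were called. Fold changes on this scale understate the change of low genes. The contrasts were spinal cord against cortex in acute and in cultured libraries, culture against acute in each region, the interaction of these, and day 3 against day 2 within each spinal cord group. Before the data were examined, the design, the alternatives, the rule for named genes and 32 gene lists (597 genes, 578 in the table) had been fixed. The lists cover regional patterning, astrocyte state and reactivity, cell cycle, metabolism, signalling and markers of other cell types that the sort could carry along, and 31 had at least 5 genes kept. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance 1 way and does not compare them with other genes. The calls that held with an estimated correlation are given as such beside each list. Members were also counted with p-values adjusted over the list alone. Differences of paired comparisons were correlated across genes without a p-value.

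The genes named for each comparison were the 8 with the largest higher and the 8 with the largest lower difference among those that passed, had a mean of at least 20 normalised counts in the higher group and did not overlap between the groups, leaving out predicted and clone names (5 and 5 for the interaction and the ages). Added were up to 4 genes per described list with the smallest adjusted p, up to 2 that went against the list or did not pass, and always Atp1b2, Gfap, Foxg1, Ascl1 and Neurog2. For groups with 1 to 3 reads of a gene, the ratio of recovered reads is given with an exact 95% interval, and a group with no read is set at a floor of 3 reads over the group. Genes that lie antisense to or overlap others, and genes with near-identical copies, are named as uncertain.

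Alternatives were a pseudocount of 0.5 or 5, no filter on low values or one of 20, libraries rescaled to the same total, quantile normalisation, no mean-variance trend, a fit of the compared groups alone, a term for age within spinal cord, the replicate number as a block, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, and leaving out each of the 21 libraries. Added after seeing the data were a fit without the 2 spinal cord acute libraries under 350000 reads and estimated library weights. The tests were tried on simulated reads for the 14019 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The reads were drawn with 1 mean per gene over all libraries, the real depths and the spread that edgeR estimated, which favours the count models. Fewer genes were changed than were called in the real regional and culture comparisons. For acute spinal cord against cortex, limma recovered 35% of the 2-fold and 85% of the 4-fold genes, edgeR 42% and 89% and DESeq2 41% and 86%. For the cultured regions limma recovered 31% and 73%, edgeR 50% and 95% and DESeq2 48% and 90%. For culture in cortex the shares were 39% and 69% in limma, 58% and 91% in edgeR and 54% and 88% in DESeq2, and for culture in spinal cord 49% and 75%, 59% and 90%, and 52% and 88%. False calls among unchanged genes, in limma, edgeR and DESeq2, were 4, 6 and 6 for the acute regions and 0, 7 and 3 for the cultured regions. They were 0, 11 and 6 for culture in cortex and 2, 8 and 7 for culture in spinal cord. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.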

Results

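The series measured RNA in mouse astrocytes, the main supportive glial cells of the brain and spinal cord, taken from the cortex or from the spinal cord of newborn pups. Astrocytes were purified on magnetic columns with an antibody against ACSA-2, a surface antigen carried by the sodium pump subunit that Atp1b2 encodes. RNA was extracted either directly after the sort (acute) or after 7 days in medium with serum, B27 supplement and the growth factors EGF and FGF, followed by trypsin and an overnight replating (culture). The labels place 5 libraries in cortex acute, 5 in cortex culture, 6 in spinal cord acute and 6 in spinal cord culture, and 5 of the last group could be matched to a column of values and were analysed. Cortex cells came from pups of postnatal day 6 and spinal cord cells from pups of day 2 or 3, so region and age go together in every comparison between the regions. Spinal cord libraries of day 2 and of day 3 came from different pups. For libraries of the same group and age, the labels do not say whether they came from separate animals or cultures. The p-values therefore measure the spread between these libraries, which may be technical.

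Whole reads recovered from the deposited values ranged from 150498 in spinal cord acute library 5 to 5777736 in cortex acute library 4, with a median of 1519423. The groups spanned 505149 to 5777736 reads in cortex acute, 1728327 to 3441761 in cortex culture, 150498 to 1519423 in spinal cord acute and 730057 to 3217068 in spinal cord culture. A count of 0 allows up to 0.626 normalised counts in the deepest library and up to 24.9 in the shallowest, at 3 reads. Such floors and the intervals given for low read counts cover counting error only. The first principal component held 37.6% of the variance and parted acute from cultured libraries. The second (15.2%) set spinal cord acute library 5 apart, and the third (9.56%) set apart spinal cord acute library 2, the next shallowest with 311898 reads. Mitochondrially encoded transcripts took 4.56% ± 0.751 (SD, n = 5) of reads in cortex acute, 3.66% ± 0.743 (n = 5) in cortex culture, 4.16% ± 1.03 (n = 6) in spinal cord acute and 2.40% ± 0.796 (n = 5) in spinal cord culture. Ribosomal protein transcripts took 7.09% ± 0.936, 9.14% ± 1.56, 6.18% ± 0.782 and 10.4% ± 0.878 in the same order of groups.

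Genes are named by symbol, with the Ensembl identifier of the deposited table for a few. The first comparison asked how astrocytes of the 2 regions differed directly after the sort. Hox genes, the transcription factors that mark position along the body axis, were far higher in spinal cord. Hoxc5 (ENSMUSG00000022485) read 249 ± 42.8 normalised counts (SD, n = 6) there and 1.09 ± 1.52 (n = 5) in cortex, and Hoxb7 read 49.9 ± 11 against 0.49 ± 0.75. Factors that pattern the forebrain showed the opposite, with Foxg1 (ENSMUSG00000020950) at 50.2 ± 10.5 in cortex and 1.27 ± 2.02 in spinal cord, and Lhx2 at 94.6 ± 30.0 against 1.92 ± 1.65. Outside these families, Col14a1, a fibril-associated collagen, read 95.8 ± 27.6 in spinal cord and 1.35 ± 0.838 in cortex. Cilium genes of ependymal cells, the ciliated lining of the ventricles and central canal, were also higher in spinal cord.

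Of 21 measured Hox genes, 20 were higher in spinal cord and 1 did not pass, and the count adjusted over the list alone was also 20. The median difference was 3.87 on the log2(value + 1) scale, and 3.94 with Hoxd9, which had no read in cortex acute, at its bound. Here and below, a bound is the log2 of a ratio of reads while the other genes keep the log2(value + 1) scale. Medians given with a bound therefore mix the scales. Errors of log2 differences are standard errors (SE) from limma, and those of levels are SDs. The Hox list test gave camera adjusted p = 1.3e-48, and adjusted p = 2.8e-08 with an estimated correlation. Hoxc5 differed by 7.19 ± 0.35 (SE, limma adjusted p = 1.3e-13), Hoxb7 by 5.18 ± 0.32 (limma adjusted p = 1.7e-11) and Hoxb6 by 5.40 ± 0.35 (limma adjusted p = 3.3e-11), while Hoxb3 differed by 0.54 (limma adjusted p = 0.43). Hoxb8 had 2 reads in cortex acute, and its ratio was 188 with a 95% counting interval of 51.1 to 1567. The transcripts Hotairm1 (6.06 ± 0.33) and Hoxb5os (4.93 ± 0.39), which lie among Hox genes, and Hopxos (5.02 ± 0.34), antisense to the homeobox gene Hopx, were also far higher in spinal cord, but these values are uncertain because the strand used in counting is not given in the sources used here. Of 11 measured forebrain patterning factors, 8 were lower in spinal cord, 0 higher and 3 did not pass, and adjusted over the list alone 8 were lower and 1 higher. Their median was -3.45, or -3.85 with Fezf2 at its bound. The forebrain factor test gave camera adjusted p = 1.1e-13, and adjusted p = 0.0003 with an estimated correlation. Lhx2 differed by -5.24 ± 0.42 and Foxg1 by -4.90 ± 0.46 (limma adjusted p = 1.3e-09 and 1.6e-08). Emx2, a cortical patterning factor, was represented by 1 read in spinal cord acute, a ratio of 186 with a 95% counting interval of 33.3 to 7370, and Bcl11a differed by -0.38 (limma adjusted p = 0.65). Nr2e1, a nuclear receptor of forebrain stem cells, was higher in cortex by a ratio of 84.4 (95% counting interval 28.7 to 410).

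Among 11 measured transcription factors that divide the ventricular zone of the embryonic spinal cord into domains, 5 were higher in spinal cord and 6 did not pass, and adjusted over the list alone 7 were higher and 1 lower. Nkx6-1 differed by 4.18 ± 0.39, Pax3 by 2.00 ± 0.32, Irx5 by 2.03 ± 0.43 and Irx3 by 1.81 ± 0.39 (largest limma adjusted p = 0.003). The list's median was 1.33. The ventricular zone test gave camera adjusted p = 3.3e-06, and adjusted p = 0.0059 with an estimated correlation. Of 13 ependymal markers, 10 were higher in spinal cord and 3 did not pass, and 12 were higher adjusted over the list alone. Foxj1, the regulator of motile cilia, differed by 2.12 ± 0.26, the cilium gene Tekt1 by 3.51 ± 0.47 and Fam183b by 3.09 ± 0.33, with a list median of 1.57. The ependymal test gave camera adjusted p = 2.1e-14, and adjusted p = 0.014 with an estimated correlation. Oligodendrocyte markers were higher for 4 of 9 genes, 4 adjusted over the list alone, including the myelin genes Mobp (3.85 ± 0.56) and Mbp (3.66 ± 0.70), with a median of 1.64. The oligodendrocyte test gave camera adjusted p = 9.1e-05, but adjusted p = 0.25 with an estimated correlation.

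Of 39 genes of mature astrocytes, 9 were higher in spinal cord, 8 lower and 22 did not pass, and adjusted over the list alone 16 were higher and 10 lower. Their median was 0.24. The mature astrocyte test gave camera adjusted p = 0.0168, but adjusted p = 0.615 with an estimated correlation. The call was also lost without cortex acute library 1 (0.106), without cortex acute library 3 (0.051) and without spinal cord acute library 4 (0.0617). Slc6a11, a GABA transporter, was higher in spinal cord by 1.68 ± 0.15 and S100b by 1.86 ± 0.26, whereas Slc1a3, a glutamate transporter (-1.26 ± 0.15), and Mfge8 (-1.25 ± 0.18) were lower (limma adjusted p = 5.4e-09, 1.9e-05, 1.7e-06 and 2.7e-05). Among 17 radial glia and neural stem cell genes, Hopx was higher in spinal cord by 2.30 ± 0.19, and 5 were lower, among them Ptprz1 (-1.77 ± 0.15) and Cspg5 (-1.55 ± 0.14), while 11 did not pass, and adjusted over the list alone 3 were higher and 7 lower. The radial glia test gave camera adjusted p = 0.064. Slc6a9, a glycine transporter, was higher in spinal cord by 2.39 ± 0.43, and the glutamate receptor gene Grm3 was lower at -1.65 ± 0.28 (limma adjusted p = 0.00039 and 0.0002). In their list of 19 genes of transmitter uptake and metabolism, 2 were higher, 6 lower and 11 did not pass, or 4 higher and 6 lower adjusted over the list alone. The transmitter gene test gave camera adjusted p = 0.50. Cholesterol synthesis genes were lower in spinal cord for 11 of 21, 12 adjusted over the list alone, including Hmgcs1 (-1.13 ± 0.23) and Msmo1 (-0.77 ± 0.16), with a median of -0.68. The cholesterol synthesis test gave camera adjusted p = 2.2e-08, but adjusted p = 0.21 with an estimated correlation. Lower in spinal cord were also Hgf, the growth factor ligand of Met (-4.48 ± 0.43), Chrdl1, a secreted BMP antagonist (-4.48 ± 0.50), and Dio2, which activates thyroid hormone (-4.29 ± 0.48; largest limma adjusted p = 5.2e-07).

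Gfap, the intermediate filament of astrocytes, read 396 ± 161 in spinal cord and 196 ± 38.3 in cortex and did not pass (limma adjusted p = 0.069), but passed without spinal cord acute library 2 (0.0374), spinal cord acute library 5 (0.0236), both of these (0.00538) or spinal cord culture library 6 (0.025). The proneural factor Ascl1 read 30.2 ± 7.26 against 16.3 ± 8.73 and did not pass (limma adjusted p = 0.115), but passed without cortex acute library 5 (0.0474) or spinal cord acute library 5 (0.048), in edgeR (0.0234) and in DESeq2 (0.0298). Atp1b2 read 760 ± 193 against 554 ± 113 (limma adjusted p = 0.18).

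Of 5 erythroid (red blood cell) genes, 4 were lower in acute spinal cord, 5 adjusted over the list alone, with Hba-a1 at -1.77 ± 0.24 and Hbb-bs at -1.48 ± 0.25, values that are uncertain because the globin genes have near-identical copies. The erythroid test gave camera adjusted p = 1.3e-07, but adjusted p = 0.088 with an estimated correlation. Of 15 endothelial markers, 2 were lower and 3 adjusted over the list alone, with a median of -0.64. The endothelial test gave camera adjusted p = 0.00096, but adjusted p = 0.21 with an estimated correlation. Of 11 mural cell markers, 4 were lower and 7 did not pass, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.064). Immediate early genes, which respond within minutes to stimulation, were higher in spinal cord for 5 of 20, 6 adjusted over the list alone, led by Socs3 (2.00 ± 0.25) and Ier2 (0.87 ± 0.19), with a median of 0.42. The immediate early test gave camera adjusted p = 0.0013, but adjusted p = 0.25 with an estimated correlation.

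Across all 14019 genes tested with limma at a Benjamini-Hochberg adjusted p of 0.05, 1018 differed between the acute groups, 560 higher and 458 lower in spinal cord, and 689 of them by at least 1 on the log2 scale. Among all 14019 genes the libraries of the groups did not overlap in 832, where chance gives 0.433% of genes. With estimated library weights, an alternative chosen after seeing the data, 1872 genes passed. Region could not be separated from the age of the pups, and 2 of the 6 spinal cord libraries held under 350000 reads.

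**Figure D1:**
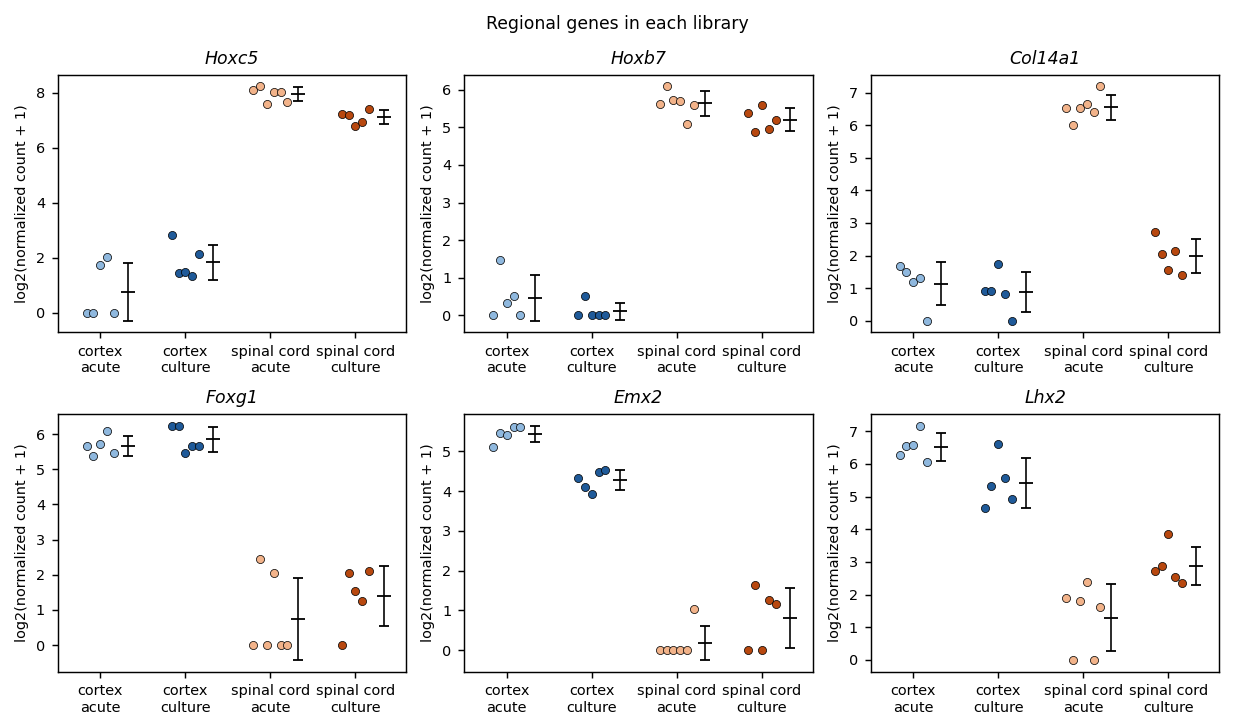
Levels of Hoxc5, Hoxb7, Col14a1, Foxg1, Emx2 and Lhx2 in each library (dots, log2 of normalised count plus 1), by group, with the group mean and SD beside the dots. Hoxc5 and Hoxb7 stay higher in spinal cord and Foxg1 in cortex in both acute and cultured groups, while Col14a1 has a mean of 95.8 normalised counts in spinal cord acute and 3.14 in spinal cord culture.

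The second comparison asked how the regions differed after culture. Position genes again differed widely. Hoxc5 read 139 ± 23.2 normalised counts (SD, n = 5) in spinal cord culture and 2.90 ± 1.94 (n = 5) in cortex culture, and Foxg1 read 1.95 ± 1.36 against 58.1 ± 15.1. Genes of the cell cycle were higher in spinal cord culture. Hmox1, the heme-degrading enzyme induced by oxidative stress, was lower there at 97.1 ± 55.9 against 690 ± 145, as was Nrn1, a neurite growth protein, at 3.16 ± 2.00 against 65.9 ± 26.0.

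Of 21 Hox genes, 18 were higher in spinal cord culture and 3 did not pass, and 20 were higher adjusted over the list alone, with a median of 3.15. The Hox list test gave camera adjusted p = 1.5e-53, and adjusted p = 1.3e-08 with an estimated correlation. Hoxc5 differed by 5.27 ± 0.36, Hoxa10 by 4.77 ± 0.37 and Hoxa7 by 4.68 ± 0.37 (largest limma adjusted p = 2.2e-09). Hoxb7 had 1 read in cortex culture, and its ratio was 296 with a 95% counting interval of 52.6 to 11760. Of 11 forebrain patterning factors, 7 were lower and 4 did not pass, also 7 adjusted over the list alone, with a median of -2.35, or -2.55 with Fezf2 at its bound. The forebrain factor test gave camera adjusted p = 1.6e-14, and adjusted p = 0.00021 with an estimated correlation. Foxg1 differed by -4.46 ± 0.48, Emx2 by -3.46 ± 0.38 and Otx1 by -2.82 ± 0.37, Dmrta2 was higher in cortex culture by a ratio of 69.5 (95% counting interval 19.0 to 578), and Nr2f1 differed by -0.18 (limma adjusted p = 0.72). Spinal ventricular zone factors were higher for 4 of 11, with 7 higher and 1 lower adjusted over the list alone, led by Nkx6-1 (3.28 ± 0.41), Pax3 (1.86 ± 0.34) and Irx5 (1.99 ± 0.44), and their median was 0.84. The ventricular zone test gave camera adjusted p = 5.1e-07, and adjusted p = 0.0019 with an estimated correlation.

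Of 37 cell cycle genes, 25 were higher in spinal cord culture, 0 lower and 12 did not pass, and 33 were higher adjusted over the list alone. Birc5, which acts in chromosome segregation, differed by 1.86 ± 0.22, the ribonucleotide reductase gene Rrm1 by 1.24 ± 0.15, the replication helicase gene Mcm6 by 1.34 ± 0.18 and the cyclin gene Ccna2 by 1.89 ± 0.26 (largest limma adjusted p = 2.4e-05). The list's median was 1.34. The cell cycle test gave camera adjusted p = 7.7e-42, and adjusted p = 0.0012 with an estimated correlation. Microglia, which also divide in culture, were measured beside it: of 18 microglia markers 0 passed in limma, also 0 adjusted over the list alone, with a median of 0.75 and a camera adjusted p of 0.00851. That call was lost with an estimated correlation (adjusted p = 0.582), without cortex culture library 3 (0.122) and without spinal cord culture library 4 (0.356). Among these 18 markers, Ly86 differed by 1.34 ± 0.50 (limma adjusted p = 0.18).

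Of 17 targets of NRF2, the transcription factor of the oxidative stress response, 5 were lower in spinal cord culture and 12 did not pass, 6 lower adjusted over the list alone. Hmox1 differed by -2.95 ± 0.51, and the glutathione transferase genes Gstm1 and Gsta4 by -1.51 ± 0.27 and -0.77 ± 0.17, with a median of -0.47. The NRF2 test gave camera adjusted p = 6.2e-08, and adjusted p = 0.00056 with an estimated correlation. Targets of YAP and SRF, regulators of the actin cytoskeleton, were higher for 8 of 18, with 8 higher and 1 lower adjusted over the list alone, among them the contractile genes Cnn1 (2.19 ± 0.30), Cnn2 (1.54 ± 0.29), Tagln (1.45 ± 0.28) and Acta2 (1.58 ± 0.32), with a median of 0.58. The YAP and SRF test gave camera adjusted p = 1.3e-06, but adjusted p = 0.14 with an estimated correlation. Tagln and Acta2 are also among 11 mural cell markers, of which 3 were higher and 8 did not pass, 3 adjusted over the list alone. The mural cell test gave camera adjusted p = 0.15. Cholesterol synthesis genes were lower for 7 of 21, with 15 lower and 1 higher adjusted over the list alone, including Fdft1 (-1.04 ± 0.20) and Msmo1 (-0.77 ± 0.17), with a median of -0.77. The cholesterol synthesis test gave camera adjusted p = 2.9e-11, but adjusted p = 0.11 with an estimated correlation.

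Mature astrocyte genes were higher for 1 and lower for 6 of 39, 1 and 7 adjusted over the list alone, with F3, which encodes tissue factor, at -1.51 ± 0.19, Mlc1 at -1.01 ± 0.17 and Slc1a3 at -0.68 ± 0.16. The mature astrocyte test gave camera adjusted p = 0.0044, but adjusted p = 0.52 with an estimated correlation. The glutamine transporter gene Slc38a3 was lower at -1.83 ± 0.20 (limma adjusted p = 5.1e-07). Of 11 pan-reactive astrocyte genes, a set raised after several injuries, S1pr3 was lower (-1.47 ± 0.32) and 10 did not pass, 2 lower adjusted over the list alone. The pan-reactive test gave camera adjusted p = 0.0052, but adjusted p = 0.077 with an estimated correlation. Of 11 ischaemia-type reactive genes, Ptx3 (-1.69 ± 0.28) and Ptgs2 (-2.46 ± 0.58) were lower, also 2 adjusted over the list alone. The ischaemia-type test gave camera adjusted p = 0.017, but adjusted p = 0.13 with an estimated correlation. Outside the lists, the secreted factor gene C1qtnf3 was higher in spinal cord culture by 4.46 ± 0.58, whereas Chil1, a chitinase-like protein of reactive glia (-3.63 ± 0.49), Glycam1, a mucin (-3.34 ± 0.59), and Gsta1, a glutathione transferase (-3.13 ± 0.52), were lower (largest limma adjusted p = 0.0007). Gfap read 474 ± 325 in spinal cord culture and 747 ± 250 in cortex culture (limma adjusted p = 0.22, and 0.0213 without spinal cord culture library 6), Ascl1 17.1 ± 5.52 and 11.4 ± 6.82 (limma adjusted p = 0.46), and Atp1b2 142 ± 35.3 and 199 ± 52.0 (limma adjusted p = 0.26).

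In limma 561 genes differed between the cultured groups, 300 higher and 261 lower in spinal cord, 365 of them by at least 1 on the log2 scale. The libraries of the groups did not overlap in 852 of all 14019 genes, where chance gives 0.794%. Count models on the recovered reads passed more genes, 1106 in edgeR and 1041 in DESeq2, and limma with estimated library weights passed 1388. The spinal cord cultures came from pups of day 2 or 3 and the cortex cultures from day 6.

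The regional differences before and after culture were then set against each other over the 14019 genes. Hox genes were higher in spinal cord and forebrain patterning factors higher in cortex in both, and the calls shared between the comparisons numbered 95 higher in spinal cord, where 12 would be shared by independent lists, and 64 lower, where 8.53 would be. Both comparisons use the same estimate of the spread of each gene, so their calls are not independent. The numbers for independent lists are a reference only. Opposite calls numbered 10 genes higher in spinal cord acute and lower in spinal cord culture, and 3 the other way. The differences correlated across genes with a Pearson r of 0.325 and a Spearman rho of 0.169, where genes are not independent replicates and the comparisons share no library. Among the 560 genes higher in acute spinal cord, the median was 1.45 before and 0.28 after culture, and 412 (73.6%) kept their sign. Among the 458 lower genes, the medians were -1.21 and -0.22, and 312 (68.1%) kept their sign.

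**Figure D2:**
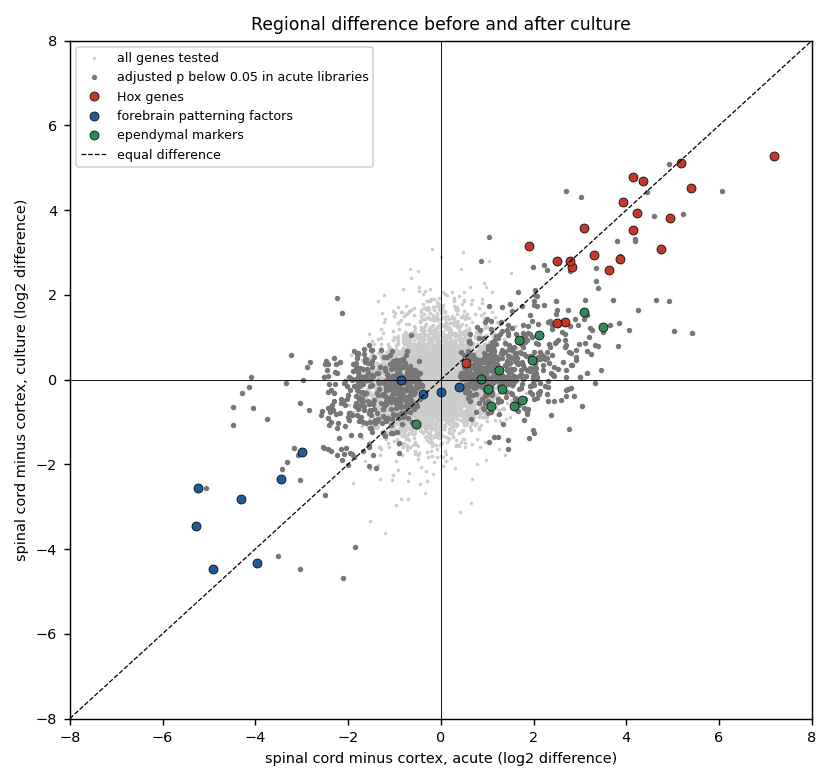
Difference between spinal cord and cortex (log2) in acute libraries (x axis) and in cultured libraries (y axis), 1 point per gene, with Hox genes in red, forebrain patterning factors in blue, ependymal markers in green and a dashed line of equal differences. Hox genes have medians of 3.87 acute and 3.15 cultured, and across all genes the Pearson r is 0.325.

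The third comparison asked what culture changed in cortical astrocytes. Hmox1 rose from 17.6 ± 4.22 to 690 ± 145 normalised counts (SD, n = 5 each), Gfap from 196 ± 38.3 to 747 ± 250, and the actin-binding contractile gene Tagln from 48.9 ± 9.28 to 966 ± 466. Genes of mature astrocytes fell together with genes of transmitter uptake, and Atp1b2, which carries the sorting antigen, fell from 554 ± 113 to 199 ± 52.0. Markers of endothelial cells and red blood cells also fell, with the tight junction gene Cldn5 at 549 ± 164 in acute and 4.81 ± 1.60 in cultured libraries and the uncertain globin gene Hba-a1 at 5118 ± 1722 and 155 ± 19.7.

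Of 39 mature astrocyte genes, 35 fell in cortical culture, 2 rose and 2 did not pass, with 36 lower and 2 higher adjusted over the list alone and a median of -2.16. The mature astrocyte test gave camera adjusted p = 2.1e-25, and adjusted p = 0.0031 with an estimated correlation. Among those that fell were the glutamate transporter gene Slc1a2 (-3.97 ± 0.20 on the log2 scale), the claudin gene Cldn10 (-3.77 ± 0.14), Slc6a11 (-2.85 ± 0.15) and the secreted matrix protein gene Sparcl1 (-2.81 ± 0.16; largest limma adjusted p = 2.9e-13). F3 (2.04 ± 0.19) and Gfap (1.87 ± 0.32, limma adjusted p = 4.9e-05) rose. Of 19 genes of transmitter uptake and metabolism, 17 fell, 0 rose and 2 did not pass, 18 lower adjusted over the list alone, with Slc6a1, another GABA transporter, at -3.23 ± 0.17 and the glutamine synthetase gene Glul at -2.84 ± 0.17, a median of -2.51, and Gls at -0.23 (limma adjusted p = 0.79). The transmitter gene test gave camera adjusted p = 7.4e-19, and adjusted p = 0.003 with an estimated correlation. Of 17 radial glia and neural stem cell genes, 8 fell and 3 rose, 10 and 3 adjusted over the list alone. The Notch target Hes5 (-3.97 ± 0.15), Cspg5 (-3.64 ± 0.14) and Ptprz1 (-3.44 ± 0.15) fell, and the intermediate filament genes Vim (2.79 ± 0.14) and Nes (1.42 ± 0.34) rose. The radial glia test gave camera adjusted p = 2.2e-05, and adjusted p = 0.0079 with an estimated correlation. Among forebrain patterning factors 5 of 11 fell, 6 adjusted over the list alone, including Nr2f1 (-1.42 ± 0.16) and Nr2f2 (-1.23 ± 0.27), while Foxg1 read 50.2 ± 10.5 and 58.1 ± 15.1 (limma adjusted p = 0.80). The forebrain factor test gave camera adjusted p = 0.023, but adjusted p = 0.17 with an estimated correlation. Ascl1 did not pass (-0.52, limma adjusted p = 0.31), and Neurog2, another proneural factor, was not kept by the filter on low values, with 18 reads over the cortex acute libraries and 0 over the cortex cultures.

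Of 11 pan-reactive genes, 9 rose and 2 did not pass, 9 adjusted over the list alone, including the small heat shock gene Hspb1 (3.54 ± 0.24) and the protease inhibitor gene Timp1 (2.89 ± 0.28), with a median of 2.06. The pan-reactive test gave camera adjusted p = 6e-07, and adjusted p = 0.003 with an estimated correlation. Of 11 ischaemia-type reactive genes, 6 rose and 5 did not pass, 6 adjusted over the list alone, including Tm4sf1 (2.90 ± 0.17), S100a10 (3.37 ± 0.20) and Cd109 (3.57 ± 0.22), with a median of 2.90. The ischaemia-type test gave camera adjusted p = 1.4e-05, and adjusted p = 0.0055 with an estimated correlation. Of 11 LPS-type reactive genes, a set raised after bacterial lipopolysaccharide, 1 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.50), and 4 rose with quantile normalisation. Of 18 YAP and SRF targets, 14 rose and 4 did not pass, 14 adjusted over the list alone, with Thbs1, a secreted thrombospondin, at 4.44 ± 0.36, Tagln at 4.17 ± 0.28, Ccn2 at 3.97 ± 0.40 and a median of 1.81. The YAP and SRF test gave camera adjusted p = 1.6e-09, and adjusted p = 0.04 with an estimated correlation. Of 17 NRF2 targets, 9 rose and 8 did not pass, with 11 higher and 1 lower adjusted over the list alone, led by Hmox1 (5.22 ± 0.51) and the pentose phosphate genes Taldo1 (0.92 ± 0.14) and Pgd (1.13 ± 0.20), with a median of 0.91. The NRF2 test gave camera adjusted p = 6.6e-05, and adjusted p = 0.0059 with an estimated correlation. The largest other rises were in Cst6, a protease inhibitor (4.73 ± 0.47), the cytokine gene Clcf1 (4.64 ± 0.49), the FOS-family factor Fosl1 (4.56 ± 0.52), Igfbp3, which binds insulin-like growth factors (4.45 ± 0.15), and the TWEAK receptor gene Tnfrsf12a (4.39 ± 0.16, largest limma adjusted p = 1.4e-07).

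Immediate early genes fell for 16 of 20, 17 adjusted over the list alone, with Fos at -2.39 ± 0.18, Junb at -2.04 ± 0.19, Egr1 at -2.15 ± 0.22 and a median of -1.14. The immediate early test gave camera adjusted p = 2.8e-08, and adjusted p = 0.023 with an estimated correlation. Of 15 endothelial markers, 14 fell and 1 did not pass, 14 adjusted over the list alone, with Cldn5 at -6.56 ± 0.24, the receptor gene Flt1 at -3.11 ± 0.28 and a median of -2.94. The endothelial test gave camera adjusted p = 2.2e-15, and adjusted p = 0.003 with an estimated correlation. Of 11 mural cell markers, 9 fell and 2 rose, also 9 and 2 adjusted over the list alone. Vtn (-3.82 ± 0.18) and the pericyte gene Rgs5 (-3.76 ± 0.21) fell, and the contractile genes Tagln and Acta2 (2.34 ± 0.32) rose. The mural cell test gave camera adjusted p = 3.2e-06, and adjusted p = 0.023 with an estimated correlation. All 5 erythroid genes fell, 5 adjusted over the list alone, with a median of -4.84, and Hba-a1 fell by 4.97 ± 0.25. The erythroid test gave camera adjusted p = 1.2e-09, and adjusted p = 0.023 with an estimated correlation. Oligodendrocyte precursor markers fell for 6 of 11, 6 adjusted over the list alone, including Olig1 (-1.30 ± 0.18) and Cspg5, a gene also on the radial glia list, with a median of -1.30. The oligodendrocyte precursor test gave camera adjusted p = 9.5e-05, but adjusted p = 0.091 with an estimated correlation. Cell cycle genes fell for 9 of 37 and rose for 2, 9 and 2 adjusted over the list alone, with Top2a at -1.37 ± 0.26, Mki67 at -1.11 ± 0.21 and the growth factor-responsive cyclin gene Ccnd1 at 2.01 ± 0.27. The cell cycle test gave camera adjusted p = 0.00615, but adjusted p = 0.512 with an estimated correlation and 0.0505 without cortex culture library 1. Ribosomal protein genes rose for 26 of 43, 30 adjusted over the list alone, with a median of 0.54, for example Rpl24 (0.86 ± 0.16) and Rps16 (0.84 ± 0.16). With quantile normalisation 9 rose, with a median of 0.19. The ribosomal protein test gave camera adjusted p = 5.1e-08, but adjusted p = 0.44 with an estimated correlation. Other losses were of St6galnac5, a sialyltransferase (-4.84 ± 0.38), Pglyrp1, a peptidoglycan-binding protein (-4.56 ± 0.38), and Dio2 (-4.55 ± 0.51; largest limma adjusted p = 8.1e-08).

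In limma 4562 genes differed between cultured and acute cortical libraries, 2355 higher and 2207 lower in culture, and 2701 by at least 1 on the log2 scale. In 3839 of all 14019 genes the libraries did not overlap, where chance gives 0.794%. Rescaling each library to the same total shifted the median of all genes by -0.135 on the log2 scale and gave 1748 higher and 2589 lower, with no called list changing the sign of its median, and estimated library weights passed 7901 genes. Culture went together with serum, growth factors, trypsin and replating, which this design does not separate.

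**Figure D3:**
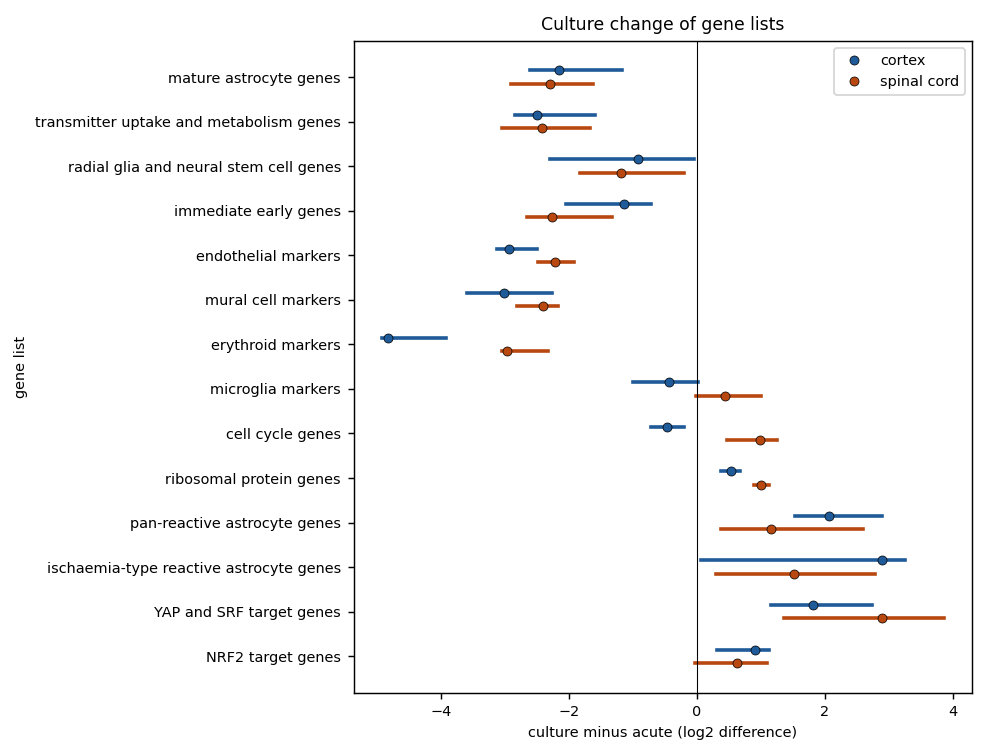
Change between acute and cultured libraries (log2) for 14 gene lists, with the median of the list's genes as a dot and their interquartile range as a bar, cortex in blue and spinal cord in orange. Mature astrocyte genes have medians of -2.16 and -2.29 and YAP and SRF targets of 1.81 and 2.89 in cortex and spinal cord.

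The fourth comparison asked the same of spinal cord astrocytes. Tagln rose from 61.2 ± 20.8 normalised counts (SD, n = 6) to 2615 ± 1155 (n = 5), and Shh, the secreted ligand Sonic hedgehog, rose from 3 reads over the acute libraries to a level of 35.2 ± 6.08, a ratio of 46.7 with a 95% counting interval of 15.7 to 228. Mature astrocyte genes fell, and Atp1b2 fell from 760 ± 193 to 142 ± 35.3. Col14a1 fell from 95.8 ± 27.6 to 3.14 ± 1.55, Cldn5 from 319 ± 41.2 to 5.46 ± 1.54 and the uncertain globin gene Hba-a1 from 1507 ± 521 to 173 ± 29.9. Gfap did not pass, at 396 ± 161 and 474 ± 325 (limma adjusted p = 0.72).

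Of 39 mature astrocyte genes, 35 fell in spinal cord culture, 1 rose and 3 did not pass, 35 and 1 adjusted over the list alone, with a median of -2.29. The mature astrocyte test gave camera adjusted p = 1.5e-27, and adjusted p = 0.0084 with an estimated correlation. Slc6a11 (-4.45 ± 0.15), the amino acid transporter gene Slc7a10 (-4.19 ± 0.22), Cldn10 (-3.77 ± 0.13) and Sparcl1 (-3.36 ± 0.15) fell, and F3 rose by 1.43 ± 0.18 (largest limma adjusted p = 6.4e-07). Of 19 genes of transmitter uptake and metabolism, 16 fell and 3 did not pass, 17 lower adjusted over the list alone, with Slc6a1 at -3.17 ± 0.17, Slc38a3 at -3.32 ± 0.19, Glul at -2.76 ± 0.17 and a median of -2.43. The transmitter gene test gave camera adjusted p = 1.2e-15, and adjusted p = 0.0091 with an estimated correlation. Of 17 radial glia and neural stem cell genes, 11 fell and 2 rose, 12 and 2 adjusted over the list alone, with Hes5 at -2.97 ± 0.15, Cspg5 at -2.10 ± 0.14, Vim at 2.32 ± 0.13 and Nes at 2.46 ± 0.32. The radial glia test gave camera adjusted p = 0.00011, and adjusted p = 0.016 with an estimated correlation. Among Hox genes 2 rose, 4 fell and 15 did not pass, 2 and 4 adjusted over the list alone, and the level of Hoxc5 was 249 ± 42.8 before and 139 ± 23.2 after culture. The Hox list test gave camera adjusted p = 0.34. Spinal ventricular zone factors rose for 1 and fell for 4 of 11, also 1 and 4 adjusted over the list alone, with Dbx2 at -2.32 ± 0.21, Olig2 at -1.16 ± 0.21 and Nkx6-1 at -1.74 ± 0.39. The ventricular zone test gave camera adjusted p = 0.050. Ependymal markers fell for 9 of 13 and rose for 1, 10 and 1 adjusted over the list alone, with Fam183b at -1.59 ± 0.33, Tmem212 at -1.31 ± 0.29 and Foxj1 at 0.90 ± 0.26. The ependymal test gave camera adjusted p = 0.011, but adjusted p = 0.35 with an estimated correlation. Ascl1 read 30.2 ± 7.26 and 17.1 ± 5.52 and did not pass (limma adjusted p = 0.075), but passed without spinal cord acute library 5 (0.028) or spinal cord culture library 6 (0.0484), in edgeR (0.0336) and in DESeq2 (0.0432).

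YAP and SRF targets rose for 14 of 18, 14 adjusted over the list alone, with Tagln at 5.34 ± 0.27, Cnn1 at 4.42 ± 0.29, Cnn2 at 3.77 ± 0.28, the actin crosslinker gene Flna at 2.29 ± 0.15 and a median of 2.89. The YAP and SRF test gave camera adjusted p = 5.8e-11, and adjusted p = 0.04 with an estimated correlation. Of 11 pan-reactive genes, 5 rose and 6 did not pass, 5 adjusted over the list alone, including Hspb1 (2.89 ± 0.23), Timp1 (2.16 ± 0.27) and the ferroxidase gene Cp (3.02 ± 0.45), with a median of 1.16. The pan-reactive test gave camera adjusted p = 0.003, and adjusted p = 0.045 with an estimated correlation. Of 11 ischaemia-type reactive genes, 6 rose, 6 adjusted over the list alone, including Tm4sf1 (2.76 ± 0.16) and Emp1 (2.37 ± 0.26), with a median of 1.52. The ischaemia-type test gave camera adjusted p = 0.00021, and adjusted p = 0.016 with an estimated correlation. LPS-type reactive genes rose for 5 of 11 and fell for 1, also 5 and 1 adjusted over the list alone (camera adjusted p = 0.12), and 3 rose with libraries rescaled. NRF2 targets rose for 9 of 17 and fell for 3, 10 and 3 adjusted over the list alone, with Hmox1 at 3.24 ± 0.49, Srxn1 at 2.59 ± 0.42, Gstm1 at -1.43 ± 0.26 and Gsta4 at -0.70 ± 0.16. The NRF2 test gave camera adjusted p = 0.094. Cell cycle genes rose for 21 of 37, 25 adjusted over the list alone and 14 with libraries rescaled, with Ccnd1 at 2.91 ± 0.26, Birc5 at 1.61 ± 0.21, Ccnb1 at 0.99 ± 0.17 and a median of 0.98. The cell cycle test gave camera adjusted p = 9.8e-06, but adjusted p = 0.22 with an estimated correlation. Microglia markers rose for 4 of 18, 1 adjusted over the list alone and 1 with libraries rescaled, for example the integrin gene Itgam (1.66 ± 0.50). The microglia test gave camera adjusted p = 0.35. Ribosomal protein genes rose for 42 of 43, 43 adjusted over the list alone, with Rps6 at 1.64 ± 0.16, Rpl6 at 1.22 ± 0.15 and a median of 1.0. With quantile normalisation 32 rose, with a median of 0.45. The ribosomal protein test gave camera adjusted p = 2.9e-16, but adjusted p = 0.20 with an estimated correlation. Other rises were of Cyp1b1, a cytochrome of xenobiotic and retinoid metabolism (4.74 ± 0.40), the collagen gene Col8a1 (4.53 ± 0.47), the matricellular gene Ccn5 (4.45 ± 0.39), the integrin gene Itga3 (4.43 ± 0.45) and Elobl (5.22 ± 0.52), which has near-identical copies and is uncertain.

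Immediate early genes fell for 18 of 20, 18 adjusted over the list alone, with Fos at -3.07 ± 0.17, Nr4a1 at -3.82 ± 0.28 and a median of -2.27. The immediate early test gave camera adjusted p = 6.7e-13, and adjusted p = 0.0091 with an estimated correlation. Endothelial markers fell for 14 of 15, 14 adjusted over the list alone, with Cldn5 at -5.65 ± 0.23, Pecam1 at -1.97 ± 0.21 and a median of -2.22. The endothelial test gave camera adjusted p = 3.3e-10, and adjusted p = 0.0091 with an estimated correlation. Mural markers fell for 9 of 11 and rose for 2, also 9 and 2 adjusted over the list alone. Rgs5 (-2.92 ± 0.20) and Notch3 (-3.83 ± 0.29) fell, and Tagln and Acta2 (3.90 ± 0.30) rose. The mural cell test gave camera adjusted p = 0.00021, but adjusted p = 0.083 with an estimated correlation. All 5 erythroid genes fell, 5 adjusted over the list alone, with Hba-a1 at -3.05 ± 0.24 and a median of -2.97, the same with Alas2, which had no read in culture, at its bound. The erythroid test gave camera adjusted p = 5.1e-06, but adjusted p = 0.092 with an estimated correlation. Oligodendrocyte precursor markers fell for 8 of 11, 9 adjusted over the list alone, including Olig1 (-1.62 ± 0.17) and Cspg4 (-1.94 ± 0.37). The oligodendrocyte precursor test gave camera adjusted p = 0.00018, but adjusted p = 0.11 with an estimated correlation. Oligodendrocyte markers fell for 6 of 9, 7 adjusted over the list alone, including Cnp (-1.37 ± 0.23) and Mobp (-2.52 ± 0.56), and spinal cord culture library 6 stood apart in their mean log2 level at 5.90 against 2.91 to 3.65 in the other libraries of its group. The oligodendrocyte test gave camera adjusted p = 0.017, but adjusted p = 0.41 with an estimated correlation. Other losses were of Slc6a9 (-4.79 ± 0.43), Col14a1 (-4.58 ± 0.38), the axon guidance gene Slit1 (-4.31 ± 0.47) and the alkaline phosphatase gene Alpl (-4.30 ± 0.30; largest limma adjusted p = 5e-08).

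In limma 6067 genes differed between cultured and acute spinal cord libraries, 3322 higher and 2745 lower in culture, and 3835 by at least 1 on the log2 scale. Non-overlapping libraries were found for 3393 of all 14019 genes, where chance gives 0.433%. Rescaling to the same total shifted the median of all genes by -0.202 and gave 2463 higher and 3504 lower, with no called list changing the sign of its median. The same limit on what culture includes held as for cortex.

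The changes with culture in the 2 regions were then set against each other. Slc6a11, Cldn10, Cldn5, Fos and Hes5 fell, and Hmox1, Tagln, Vim and Hspb1 rose, in both. Calls shared in direction numbered 1828 higher, where 558 would be shared by independent lists, and 1626 lower, where 432 would be. Here too the calls rest on the same estimate of the spread of each gene, so the numbers for independent lists are a reference only. Opposite calls numbered 25 genes higher in cortex culture and lower in spinal cord culture, and 15 the other way. Across the 14019 genes the changes correlated with a Pearson r of 0.766 and a Spearman rho of 0.746, where genes are not independent replicates and the comparisons share no library. Of the genes called higher in cortex culture 95.3% had the same sign in spinal cord, and of those called lower 95%.

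The difference between the 2 responses was tested as the interaction of region and culture, positive where the change in spinal cord exceeded that in cortex. Cyp1b1 read 2.22 in spinal cord acute and 74.5 in spinal cord culture but 12.9 and 18.5 in cortex, an interaction of 4.16 ± 0.57. St6galnac5 (4.16 ± 0.53), Dio2 (3.97 ± 0.70), the matrix link protein gene Hapln1 (3.96 ± 0.71) and Chrdl1 (3.82 ± 0.72) were high in cortex acute and low in the other groups. Col14a1 (-4.32 ± 0.55), the uncertain Hopxos (-3.88 ± 0.49) and the ion channel regulator gene Fam155a (-3.66 ± 0.51) were high in spinal cord acute and low in the other groups (largest limma adjusted p among these = 0.0025).

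Of 37 cell cycle genes, 12 passed with a positive interaction and 25 did not pass, 29 adjusted over the list alone, with Birc5 at 2.14 ± 0.30, Ccna2 at 2.10 ± 0.36, Mcm6 at 1.36 ± 0.25, Top2a at 1.81 ± 0.35 and a median of 1.45. The cell cycle test gave camera adjusted p = 1.9e-25, and adjusted p = 0.048 with an estimated correlation. The mean log2 level of the list was 4.04 to 5.09 in the cortex cultures and 5.78 to 6.01 in the spinal cord cultures, while microglia levels were 2.38 to 4.32 and 2.61 to 5.43. Of 15 endothelial markers, 0 passed, also 0 adjusted over the list alone, with a median of 0.66. The endothelial test gave camera adjusted p = 0.002, but adjusted p = 0.20 with an estimated correlation. Of 11 mural cell markers, 1 was positive, with 5 positive and 1 negative adjusted over the list alone and a median of 0.70. The mural cell test gave camera adjusted p = 0.0026, but adjusted p = 0.20 with an estimated correlation. Of 5 erythroid genes, 4 passed with positive values, 4 adjusted over the list alone, including Hba-a1 (1.92 ± 0.34). The erythroid test gave camera adjusted p = 5.5e-07, but adjusted p = 0.095 with an estimated correlation. Of 13 ependymal markers, 3 were negative, 10 adjusted over the list alone, with a median of -1.49. The ependymal test gave camera adjusted p = 2.6e-10, but adjusted p = 0.062 with an estimated correlation. Of 9 oligodendrocyte markers, 0 passed, 3 negative adjusted over the list alone, with a median of -2.10. The oligodendrocyte test gave camera adjusted p = 0.00021, but adjusted p = 0.20 with an estimated correlation. Of 17 radial glia genes, 3 passed, 3 adjusted over the list alone, namely Cspg5 (1.54 ± 0.20), Ptprz1 (1.62 ± 0.21) and Hes5 (1.0 ± 0.21). The radial glia test gave camera adjusted p = 0.064. Among transmitter genes 2 of 19 were positive and 3 negative, 4 and 4 adjusted over the list alone, with Grm3 at 2.25 ± 0.40, Slc6a11 at -1.60 ± 0.21, Slc38a3 at -1.56 ± 0.27 and Slc6a9 at -3.21 ± 0.61. The transmitter gene test gave camera adjusted p = 0.51. Of 20 immediate early genes 2 were negative, 7 adjusted over the list alone, led by Socs3 (-1.96 ± 0.36). The immediate early test gave camera adjusted p = 5.6e-08, but adjusted p = 0.062 with an estimated correlation. Of 17 NRF2 targets 2 were negative, with 5 negative and 1 positive adjusted over the list alone, led by Gsta4 (-1.85 ± 0.24). The NRF2 test gave camera adjusted p = 0.0035, but adjusted p = 0.062 with an estimated correlation. Gsta1, at 0.125 and 21.3 in cortex and 0.887 and 1.52 in spinal cord, passed in limma (-3.55 ± 0.72, limma adjusted p = 0.0052) and not in edgeR (adjusted p = 0.216). Gfap passed with -1.72 ± 0.44 (limma adjusted p = 0.0334), and its adjusted p lay between 0.0548 and 0.0764 when any 1 of cortex acute libraries 1, 2 and 3, cortex culture libraries 1, 2 and 5, spinal cord acute libraries 1, 4 and 6 or spinal cord culture libraries 1, 2 and 3 was left out, at 0.0915 with no filter and at 0.0925 with no trend. Atp1b2 did not pass (-0.92, limma adjusted p = 0.079), but passed without cortex culture library 4 (0.0377), spinal cord acute library 5 (0.0474) or spinal cord culture library 6 (0.0347).

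In limma 326 genes passed the interaction, 140 positive and 186 negative, 295 of them by at least 1 on the log2 scale. The count was 534 in edgeR, 574 in DESeq2, 497 with a pseudocount of 5, 492 without the 2 shallowest spinal cord libraries and 1076 with estimated library weights.

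**Figure D4:**
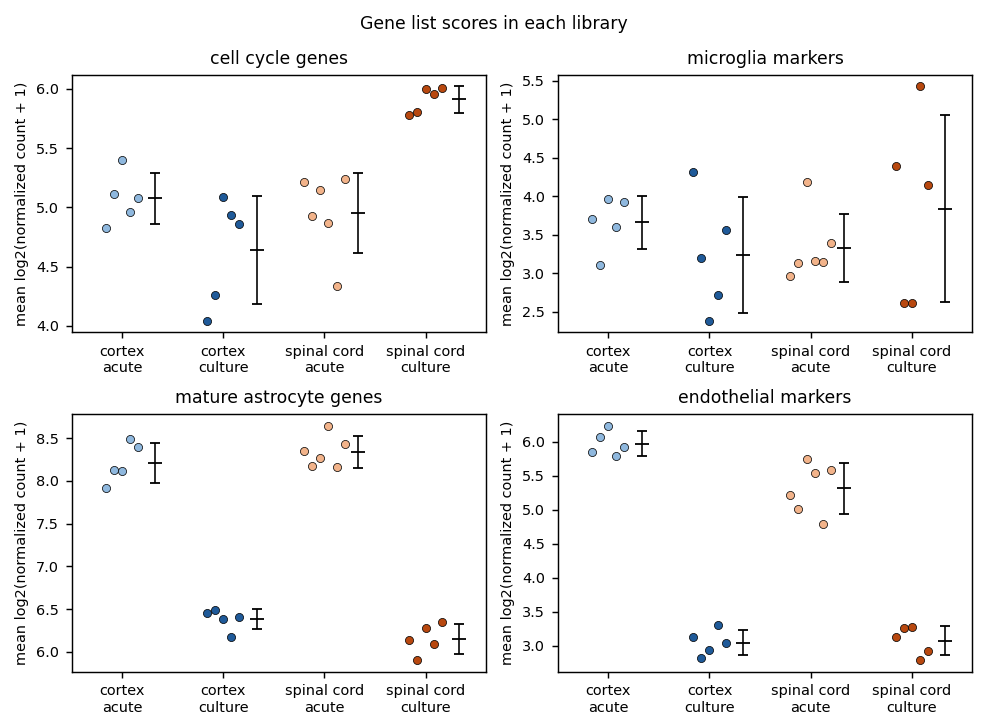
Mean log2 level of cell cycle, microglia, mature astrocyte and endothelial genes in each library (dots), by group, with group mean and SD. The cell cycle level of the cortex cultures lies between 4.04 and 5.09 and that of the spinal cord cultures between 5.78 and 6.01, and mature astrocyte and endothelial levels are lower in culture in both regions.

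Pups of day 2 and day 3 could be compared within spinal cord. In acute libraries (3 against 3), 0 genes passed in limma, with 1515 at an unadjusted p under 0.05, and edgeR and DESeq2 also passed 0. The number was 3 without spinal cord acute library 1, 15 without library 3, 7 without library 4 and 6 without library 6. In cultures (2 libraries of day 3 against 3 of day 2), 688 genes had an unadjusted limma p under 0.05. Chance gives a share of about 0.05 of the 14019 genes, which 688 did not exceed and the 1515 of the acute libraries did. The 1 gene called was Spata2, an adaptor of the tumour necrosis factor receptor complex. It was lower at day 3 (-2.94 ± 0.47, limma adjusted p = 0.0267). The count of 1 became 3 in edgeR and 4 in DESeq2, neither of which passed Spata2, 3 without cortex culture library 1 or spinal cord acute library 5, 2 without cortex culture library 3, and 0 without cortex acute library 4 or spinal cord culture libraries 4 or 6. Leaving out spinal cord culture library 2 or 3 (82 and 0 genes) tests nothing about age, since day 3 then rests on 1 library and the spread comes from the other libraries.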

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

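The tests of scaling for endothelial and cell cycle genes, of dividing microglia and of how patterning factors keep their difference were chosen only after the results they bear on were seen.

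The change with culture differed between the regions for 326 genes in limma, and for cell cycle genes by a median of 1.45 on the log2 scale. Interactions of single genes were 4.16 for Cyp1b1, 4.16 for St6galnac5, 3.97 for Dio2, 3.96 for Hapln1, 3.82 for Chrdl1, -4.32 for Col14a1, -3.88 for the uncertain Hopxos, -3.66 for Fam155a and -1.72 for Gfap. Gfap lost its call when any 1 of 12 libraries was left out (cortex acute 1, 2 and 3, cortex culture 1, 2 and 5, spinal cord acute 1, 4 and 6 and spinal cord culture 1, 2 and 3), with adjusted p-values of 0.0548 to 0.0764. Gsta1 (-3.55) and Slit1 (-3.22) passed in limma, but not in edgeR (adjusted p = 0.216 and 0.142), and Slit1 not in DESeq2 (adjusted p = 0.0746).

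Cell cycle genes were higher in spinal cord than in cortex cultures, with a median of 1.34. Directly after the sort the list was not called (camera adjusted p = 0.82), and 1 of 37 genes was lower in spinal cord. Scaling as the cause is argued against, since the median was 1.29 in the weaker of 2 other scalings. Dividing microglia are argued against as the whole cause: the spinal cord cultures of day 3 had microglia levels within the range of the cortex cultures, yet the lowest cell cycle level among them lay 0.719 above the highest of the cortex cultures. Age at isolation cannot be told apart from region, because the difference between day 3 and day 2 in spinal cord culture (median 0.0526) rests on 2 against 3 libraries and day 6 was taken from cortex alone. A regional difference in growth in this medium may be involved and was not tested separately.

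Endothelial, mural and erythroid markers were lower in culture in both regions, beside the mature astrocyte genes, but in spinal cord the mural and erythroid list calls were lost, at adjusted p = 0.083 and adjusted p = 0.092 with an estimated correlation. RNA of such cells carried along in the acute sort is a candidate explanation that the test made here cannot settle. Across the 11 acute libraries, the members of each list varied together more than most of 1000 random sets of the same level. The percentile was 99.5 for endothelial, 99.8 for mural and 100 for erythroid markers. The random sets were matched on level alone, so genes regulated together within astrocytes could also rank high. Estimated correlations between genes were 0.152 for endothelial and 0.177 for mural markers. They were 0.193 for mature astrocyte genes, 0.212 for transmitter genes and 0.843 for erythroid markers. Among the markers were Hba-a1 at 5118 ± 1722 and Cldn5 at 549 ± 164 normalised counts in cortex acute, and an ACSA-2 sort would be meant to remove these cells. Of the mural markers, 2 (Tagln and Acta2) are also on the list of YAP and SRF targets and rose, and no endothelial or erythroid marker is on another list. Scaling is argued against for the endothelial markers, which stayed 2.31 below all genes (-2.31 on the log2 scale) after rescaling, in the weaker region, while loss of transcripts within astrocytes stays open.

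Regional differences called directly after the sort were smaller in culture. Lists of other cell types took part: the regional median of ependymal markers was 1.57 acute and 0.0049 in culture. That of oligodendrocyte markers was 1.64 and 0.06. The interaction calls of both lists were lost with an estimated correlation (camera adjusted p = 0.062 and 0.20). How far other cell types in the acute sort account for the smaller differences was not tested. Selection of genes on the same libraries is argued against as the whole cause. In acute libraries not used for the calls, the median difference was still 3.26 (2.69 to 3.72) and 3.71 (3.12 to 4.74) times that in culture. The ranges in brackets come from resampling genes with the libraries held fixed. They leave out the spread between libraries and treat genes as independent. Patterning factors may keep their regional difference better than other regional genes, at ratios of culture to held-out acute difference of 0.841 against 0.258 and 0.796 against 0.269, with a permutation p of 1e-04, the smallest that 10000 permutations can give. The permutation shuffled only genes whose held-out difference lay above a fixed minimum in the called direction, and the ratios depend on that choice. These were 25 patterning factors and 358 other genes of 404 called, and 27 and 287 of 331. The permutation treats genes as independent, while neighbouring Hox genes share regulation, and genes of equal acute difference were not compared. Age at isolation cannot be told apart from region. Over 985 regional genes outside the patterning lists, day 3 minus day 2 in acute spinal cord was correlated with cortex minus spinal cord. The r was 0.0102, within the other 9 splits of the same libraries (up to 0.389 in size). The genes and both differences drew on the same spinal cord acute libraries, and genes are not independent replicates.

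Some libraries stood far from the rest of their group, 15 of 244 groups tested, where chance gives about 5% of groups. Mean log2 levels of lists that stood apart were 6.87 for pan-reactive genes in cortex culture library 5 (others up to 6.69), 5.90 for oligodendrocyte markers in spinal cord culture library 6 (others 2.91 to 3.65) and 4.18 for microglia markers in spinal cord acute library 3 (others up to 3.40). Spinal cord acute library 5, the shallowest, was lowest for oligodendrocyte precursor markers (4.25), immediate early genes (6.84) and growth factor feedback genes (3.99). In normalised counts, the gene values apart were Emx2 at 1.05 in spinal cord acute library 6, Lhx2 at 13.4 in spinal cord culture library 3, Nr2e1 and Dmrta2 at 4.5 in spinal cord acute library 2, Hoxb7 at 1.79 in cortex acute library 2 and 0.434 in cortex culture library 2, Shh at 7.84 in cortex culture library 1, Ascl1 at 16.6 in spinal cord acute library 5 and Neurog2 at 0.688 in spinal cord culture library 4. Those of Emx2, Neurog2 and Hoxb7 in cortex culture were 1 read over the whole group. Nr2e1 and Dmrta2 lay below the 13.5 that 3 reads give in that library, and Hoxb7 in cortex acute below 2.69. Such low counts cannot show that a library stood apart.

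Chance assignment of libraries was tested with 100 splits per comparison, the real one included. Chance is argued against, but not excluded, for the counts of the acute regions (1018, highest other split 587), the cultured regions (561, highest other 75), culture in cortex (4562, highest other 1258), culture in spinal cord (6067, highest other 4064) and the interaction (326, highest other 2), each matched by 1 split, the real one. A share of 1 in 100 is the smallest these splits can give. The test also takes the libraries as independent, which the labels do not say. For day 3 against day 2 in acute spinal cord there are 10 splits, too few for a share under 0.05, and all 10 gave at least the real count of 0, with 71 as the highest other.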

How the results depend on the processing

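The fit without the 2 shallowest libraries and the library weights were chosen only after the results were seen. List tests with library weights were not run. Of 677 followed gene comparisons none reversed, and the counts on the same side of the threshold were 595 in edgeR (70 gained, 12 lost), 596 in DESeq2 (69 and 12), 549 with library weights (117 and 11), 618 without the shallow pair (47 and 12), 625 with a pseudocount of 5 (47 and 5), 621 with quantile normalisation (47 and 9) and 640 with libraries rescaled (20 and 17). Of 80 list calls 29 were kept with an estimated correlation (51 lost), 65 in fry, 76 without the shallow pair, 79 with libraries rescaled and 80 with the block. Counts moved by over 1.5 times were, for the acute regions, 1872 with library weights, for the cultured regions 1106 in edgeR, 1041 in DESeq2 and 1388 with weights, for culture in cortex 7901 with weights, and for the interaction 497 with a pseudocount of 5, 534 in edgeR, 574 in DESeq2, 492 without the shallow pair and 1076 with weights, and the cause was not tested. For age in acute spinal cord the count of 0 became 4 with no filter and 2 with no trend (0 in edgeR and DESeq2, 1515 at an unadjusted limma p under 0.05). For age in spinal cord culture the count of 1 became 2 with a pseudocount of 0.5, 27 with no filter, 3 in edgeR, 4 in DESeq2, 4 without the shallow pair, 4 with weights, and 0 with a pseudocount of 5, a filter of 20, rescaling, the 2 groups alone or the block (688 at an unadjusted limma p under 0.05). The correlation of the regional differences was 0.245 with no filter, 0.3975 with a filter of 20, 0.3904 with the block, 0.426 in edgeR and 0.4234 in DESeq2, and that of the culture changes 0.7951 with a pseudocount of 5, 0.6978 with no filter, 0.8249 with a filter of 20, 0.8047 in edgeR, 0.8034 in DESeq2 and 0.7957 with weights. Leaving out 1 library gave 755 to 1085 calls for the acute regions, 404 to 716 for the cultured regions, 3864 to 5257 for culture in cortex, 5517 to 6391 for culture in spinal cord, 235 to 433 for the interaction, 0 to 15 and 0 to 82 for the ages (82 without spinal cord culture library 2, which leaves 1 library of day 3, and 15 without spinal cord acute library 3), correlations of 0.2992 to 0.3351 and 0.7471 to 0.7748, and 77 to 82 list calls. Replicate numbers gave no clear sign of pairing, but such weak correlations cannot exclude it. The correlation of same-numbered deviations was over 0.1 in 1 of 5, 2 of 4, 0 of 5 and 1 of 5 pairs (acute regions, cultured regions, cortex, spinal cord). In the same order, 3, 1, 1 and 2 libraries correlated best with their own number. Pairs of the same age numbered 0, 0, 5 and 2, and the others came from different pups. The highest correlation was 0.241, for spinal cord number 6, with both libraries of day 2 (highest with another number 0.0704). With the replicate number as a block, 1058, 583, 4852, 6139 and 404 genes passed in the regional, culture and interaction tests, and 0 for age in culture. Depth limits low genes most in the spinal cord acute libraries, where 3 reads are up to 24.9 normalised counts.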

Other observations

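The test of Hox position was chosen only after the culture change of these genes was seen, and the age and Hedgehog values were picked out after they were seen.

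Microglia markers were lower in the spinal cord cultures of day 3 than in those of day 2. Of 18 measured markers 0 passed in limma over all genes. In that comparison 688 genes had an unadjusted limma p under 0.05, no more than chance gives, and edgeR and DESeq2 called 3 and 4 genes. Adjusted over the list alone, 11 microglia markers were lower, with a list median of -2.13 (camera adjusted p = 1.3e-21, and adjusted p = 0.034 with an estimated correlation). The complement gene C1qa differed by -3.58 ± 0.83 and Tyrobp, a signalling adaptor of microglia, by -2.92 ± 0.59. Other cell type lists passed in camera in the same comparison, with none of their genes past the threshold over all genes. The medians were -0.92 for oligodendrocyte precursor markers (1 of 11 lower adjusted over the list alone, camera adjusted p = 0.00029, but adjusted p = 0.48 with an estimated correlation), 0.66 for 14 meningeal and fibroblast markers (0 over the list alone, camera adjusted p = 0.033, but adjusted p = 0.48 with an estimated correlation) and 0.27 for 15 endothelial markers (0 over the list alone, camera adjusted p = 0.049, but adjusted p = 0.67 with an estimated correlation). Lists not of cell types passed too, and all lost their call with an estimated correlation (smallest adjusted p = 0.48). Camera adjusted p was 2.6e-06 for cholesterol synthesis genes (median -0.36), 0.00029 for YAP and SRF targets (0.46) and 0.00029 for extracellular matrix genes (0.44). It was 0.004 for ribosomal protein genes (-0.19) and 0.048 for immediate early genes (0.18). Only the microglia list kept its call. All of this rests on 2 against 3 libraries.

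The ligand gene Shh rose in spinal cord culture while 9 measured Hedgehog pathway genes went both ways, with 1 higher, 2 lower and 6 not past the threshold (camera adjusted p = 0.34). The receptor and pathway target Ptch1 fell by 2.25 ± 0.28, Gas1, a co-receptor, differed by -0.90 ± 0.27 and Ptch2 rose by 1.75 ± 0.30. In cortex Shh had 5 reads over the acute libraries and 4.09 ± 2.20 normalised counts in culture (limma adjusted p = 0.0009, not followed through the alternatives). In cortex culture Ptch1 fell by 2.02 ± 0.30 and Ptch2 rose by 1.78 ± 0.31, and the list counts were the same.

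Extracellular matrix genes changed both ways in culture. In spinal cord 13 of 30 rose and 7 fell, also 13 and 7 adjusted over the list alone (camera adjusted p = 0.34), with fibronectin, Fn1, at 2.39 ± 0.16 and the proteoglycan gene Vcan at -1.88 ± 0.19. In cortex 11 rose and 7 fell, 14 and 8 adjusted over the list alone (camera adjusted p = 0.33), with Vcan at -1.81 ± 0.20 and the basement membrane gene Nid1 at -1.61 ± 0.26.

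A hypothesis that posterior Hox genes might be kept better in spinal cord culture than anterior ones was tested over 21 Hox genes. The median culture change was -0.567 for the 9 genes of paralogues up to 6 and 0.0525 for the 12 from 7 on, which were not tested against each other. The paralogue number and the culture change had a Spearman rho of 0.088 (permutation p = 0.7) and a Pearson r of 0.0578, or 0.181 without the 2 farthest genes. Genes are not independent replicates. The test leaves the hypothesis open, because neighbouring Hox genes share regulation and 21 genes are few.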
